A study of Mus musculus with 27 samples.

How the data were processed

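The deposited values are FPKM (fragments per kilobase of transcript per 1e6 mapped fragments) per the file headers and the values themselves, which are given to 2 decimals and sum to different totals in different libraries. The submitters' processing notes name HISAT, Bowtie2 and RSEM and the mouse build mm9. Versions, parameters, annotation, strand setting and the order of the tools are not given in the sources used here. The reference used here for GC content and transcript length is of another build, so no coordinates were used and genes were matched by NCBI gene ID only. The table held 21984 genes and gene models: 18885 with a symbol and 3099 models without one, which carry no name here. GC content and length were found for 18766 of those with a symbol. All 27 columns of values were used, 1 per library. Whole read numbers could not be recovered from rounded FPKM, so sequencing depth is unknown and no test on read counts was possible.

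Each library is 1 tissue of 1 mouse. The series text gives 9 animals, 3 per age, and the libraries are numbered 1 to 3 within each age and tissue. Numbers at different ages mean different animals. Within an age the same number was taken to mean the same animal in cortex, hippocampus and kidney, which was checked on the values.

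Values were taken as log2(FPKM + 1). Within each tissue, genes with a mean of at least 1 FPKM over its 9 libraries were tested. A linear model with 1 mean per age was fitted to the 9 libraries with limma 3.58.1 in R 4.3.3, with moderated two-sided tests and a variance trend over expression. P values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p below 0.05 is a call. Words such as rose, fell, higher and lower are used of single genes that were called. The 18 against 2 and 10 against 2 month comparisons share the 2-month libraries. Differences between tissues were tested as the 18 against 2 month change in one tissue minus that in another, in 1 model over all 27 libraries, on genes passing the filter in both tissues. Genes called in the same direction in several tissues were counted, with the number expected by chance and a one-sided Fisher exact test. A gene is separated when every value of one age lies above every value of the other. With 3 against 3 libraries, 10% of genes are separated by chance, or 5% in one given direction, and the smallest two-sided exact p is 0.1.

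Lists of genes for functions and cell types were written from general knowledge before the values were examined. They were tested with camera in limma (two-sided, preset correlation 0.01, at least 3 tested members), adjusted over the lists of a tissue, and again with the correlation between genes estimated from the data. Members were also adjusted over the list alone. Camera ranks a list against all other tested genes, so its direction can differ from the sign of the list's median or mean.

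Genes are named by rules fixed beforehand. C4a and C4b are always given. For 18 against 2 months in each tissue, the 6 largest rises and 6 largest falls among called and separated genes are named, and for the other age comparisons the largest 3 of each. For lists, the 2 called members with the smallest adjusted p are named (up to 4 where 6 or more are called), or else the member with the highest mean. For differences between tissues the largest 3 in each direction are named, and where nothing was called, the 3 genes with the smallest p. Predicted genes, pseudogenes and models without a symbol were passed over and counted. Of the genes picked by these rules 2 are not used here by name and were not replaced, so some comparisons name fewer; counts, lists and overlaps include them. Other members of lists named after their values were seen are said to be so and were not followed under the alternatives, and the peptides of hypothalamus and pituitary in the description of the libraries were likewise named after their values were seen. FPKM are given as mean ± SD with n = 3 animals per age, and log2 changes are differences of mean log2(FPKM + 1).

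Alternatives fixed beforehand were a pseudocount of 0.1, no expression filter, a minimum mean of 5 FPKM, scaling to a common FPKM sum per library (TPM), median-ratio scaling, quantile normalisation, array weights, a minimum fold change of 2, all 27 libraries in 1 model, the replicate number as a block, leaving out each library in turn, and the estimated camera correlation. Chosen after the data were seen were removal of each library's trend over GC content and transcript length (loess, span 0.3), genes with a symbol only, and leaving out the 2 libraries with the lowest array weights for comparisons between tissues. Every call was also counted under all 10 splits of the 6 libraries of a comparison into 3 and 3.

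The pipeline was tested on simulated data, drawn from each gene's own mean and residual spread in a tissue, with changes added to 200 genes at 18 months. At a log2 change of 1 it recovered 92.4% of them in cortex, 81.8% in hippocampus and 82.1% in kidney, and at 0.5 it recovered 63.6%, 44.8% and 28.4%. Unchanged genes were called 11, 6 and 4 times. For differences between tissues at a log2 change of 1 it recovered 88.1% (hippocampus and cortex), 87.5% (kidney and cortex) and 85.1% (kidney and hippocampus). There 38, 20 and 50 unchanged genes were called. In cortex and in all comparisons between tissues these false calls were more than 5% of all calls, so single calls there carry more error than the threshold states. The simulated noise was independent between genes and equal in all libraries of a tissue, whereas the real libraries differed in array weight and GC trend. The simulation therefore cannot show that the threshold is kept in the real data of any tissue. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.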

Results

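Gene expression was compared between C57BL/6 mice of 2, 10 and 18 months in cortex, hippocampus and kidney to find which transcripts change with age in 1 tissue, and which in all of them. Each group held 3 libraries from 3 separate mice, and the 3 tissues come from the same 9 animals. Sums of FPKM ranged from 310290.8 to 327504.4 in cortex, from 310596.5 to 330566.2 in hippocampus and from 391936.2 to 478542.5 in kidney. Genes at 1 FPKM or more numbered 12809 to 13062, 12852 to 13323 and 12108 to 12675. Kidney androgen-regulated protein (Kap) was the most abundant transcript of every kidney library, at 3.659 to 6.221% of the FPKM. The choroid plexus transcript Ttr was the most abundant of 3 hippocampus libraries (replicates 2 and 3 at 10 months and replicate 1 at 18 months) and ranged from 15.32 to 7970.64 FPKM in hippocampus. Peptides of the hypothalamus reached 242.22 FPKM (Avp), 279.55 FPKM (Oxt), 201.86 FPKM (Hcrt) and 434.11 FPKM (Pmch) in replicate 2 of hippocampus at 2 months, which had an array weight of 0.1316. Means of pituitary hormones were highest at 2 months, with Pomc at 164.6 ± 123 FPKM in hippocampus at 2 months against 5.69 ± 7.71 FPKM at 18 months (n = 3). Replicate 1 of kidney at 18 months had the highest FPKM sum and an array weight of 0.1744.

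The complement component C4 was followed first, because C4b is the main mouse C4 gene and acts in the classical pathway, which in brain also tags synapses. C4b was higher in cortex and kidney of 18-month mice than of 2-month mice. In hippocampus its values were separated by age as well, and its unadjusted p was near that in cortex. After adjustment over all genes its test was not passed there. C4a, the near-identical sex-limited copy, was too low to test.

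C4b (gene 12268) in cortex went from 5.89 ± 2.48 FPKM at 2 months through 10.0 ± 2.21 at 10 months to 15.4 ± 2.75 at 18 months (n = 3; log2 change 1.32, standard error 0.271, adjusted p = 0.0495). In kidney it went from 0.973 ± 0.33 through 1.95 ± 0.709 to 6.69 ± 1.87 FPKM (n = 3; log2 change 1.95, standard error 0.221, adjusted p = 0.00476), a ratio of means of 6.87. In hippocampus the means were 10.5 ± 3.57, 20.5 ± 7.02 and 34.05 ± 8.65 FPKM (n = 3; log2 change 1.62, standard error 0.318, adjusted p = 0.0987), with an adjusted p of 0.00605 over the complement list alone. The unadjusted limma p at 18 against 2 months was 0.000864 in hippocampus and 0.00087 in cortex. C4b was not called at 10 against 2 months (log2 0.73, 0.89 and 0.57 in cortex, hippocampus and kidney; adjusted p = 0.177, 0.19 and 0.342). It was not called at 18 against 10 months either (log2 0.58, 0.73 and 1.38; adjusted p = 0.502, 0.833 and 0.167). Its change did not differ between tissues by the test (log2 0.30 for hippocampus minus cortex, 0.63 for kidney minus cortex and 0.33 for kidney minus hippocampus; adjusted p = 1, 0.47 and 0.701). C4a (gene 625018) lay between 0.04 and 0.41 FPKM in all libraries, and how reads shared by the 2 copies were divided is not given in the sources used here. The cortex call was kept without replicate 2 at 10 months (adjusted p = 0.0429) and replicate 1 at 2 months (0.0465), and was lost without replicates 1 and 3 at 10 months (0.0783 and 0.0658), replicates 1, 2 and 3 at 18 months (0.136, 0.114 and 0.154) and replicates 2 and 3 at 2 months (0.0886 and 0.0792). The kidney call was kept whichever library was left out.

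**Figure D1:**
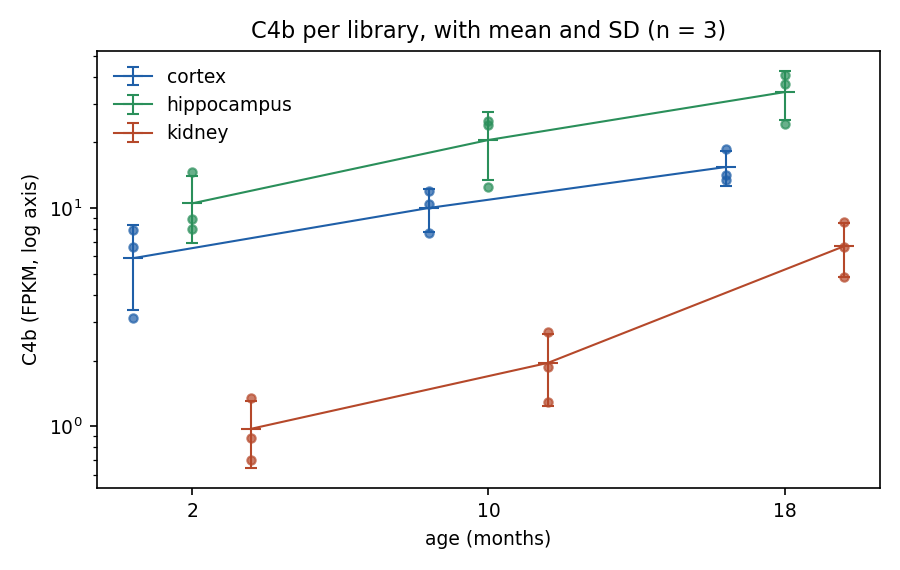
C4b in each library (points) at 2, 10 and 18 months in cortex, hippocampus and kidney, with mean and SD, on a logarithmic FPKM axis.

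In cortex the largest rises of named genes from 2 to 18 months were of heart muscle genes: the myosin light chains Myl2 and Myl3, the oxygen-binding protein Mb, cardiac actin Actc1, the myosin heavy chain Myh6 and troponin Tnni3. Among the falls were Tdg, a glycosylase of DNA repair whose values are mirrored by a model without a symbol, the pentraxin receptor Nptxr at synapses, Srp9 of the signal recognition particle and the neuroprotective homeobox gene Adnp. The growth factor Bdnf, the postsynaptic scaffold Shank3, the cell cycle inhibitor Cdkn1a and Gpr17 of maturing oligodendrocyte precursors also fell. The calls of Nptxr, Adnp, Bdnf, Cdkn1a, Gpr17, Myh6 and Tnni3 were each lost when most single libraries were left out, and that of Shank3 whichever library was left out. The complement protease C1ra rose with C4b, but each call was lost under some alternatives and when most single libraries were left out.

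This comparison asks what differs in cortex between young and old mice. Of 12976 genes tested, 238 were called, 116 higher and 122 lower. Myl2 (gene 17906) rose from 0.803 ± 0.671 to 21.3 ± 11.2 FPKM (n = 3; log2 3.52, standard error 0.433, adjusted p = 0.00767) and Mb (gene 17189) from 0.57 ± 0.353 to 17.0 ± 9.53 FPKM (n = 3; log2 3.34, adjusted p = 0.00884). Myl3 (log2 3.04, adjusted p = 0.0121), Actc1 (2.98, 0.0134), Myh6 (2.75, 0.0186) and Tnni3 (2.35, 0.0308) followed. Tdg (gene 21665) fell from 11.95 ± 0.324 to 0.797 ± 0.0451 FPKM (n = 3; log2 -2.85, standard error 0.0706, adjusted p = 8.2e-08), and Nptxr (gene 73340) from 117.7 ± 31 to 39.5 ± 0.823 FPKM (n = 3; log2 -1.52, adjusted p = 0.0471). Falls were also called for the ribosomal retrogene Rpl37rt (-1.10, 0.0299), Srp9 (-1.07, 0.0109), the transcription factor Mafg (-1.07, 0.046) and Adnp (-0.99, 0.0367). Models without a symbol made up 45 of the calls and 479 of the genes tested, and predicted genes 6 of the calls. The count was 150 and 140 without replicates 1 and 3 at 10 months, 52, 78 and 96 without replicates 1, 2 and 3 at 18 months, and 120, 112 and 53 without replicates 1, 2 and 3 at 2 months. Of the 29 named cortex genes that were called, 5 (Myl2, Mb, Tdg, Capn11 and Kcnh6) stayed called whichever library was left out.

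Some immune lists in cortex shifted upward by camera with the preset correlation, while complement, microglia, interferon response and MHC class II were not called. With an estimated correlation 0 lists were called in cortex (smallest adjusted p = 0.779), and with the preset one 6 of the 10 splits of the libraries called at least the real 10 lists (up to 16). MHC class I and antigen processing (13 genes tested, 0 called over all genes, 5 higher when adjusted over the list alone, median log2 0.257, camera adjusted p = 0.000152, highest member B2m 0.26 with adjusted p = 0.202) and macrophages and monocytes (9 tested, 1 called, 3 over the list alone, median 0.283, adjusted p = 0.000627) had the smallest camera p of these, the latter with Adgre1 (0.45, 0.038). The call of Adgre1 held under 7 of 11 alternatives and in 1 of 9 fits with a library left out. Disease-associated microglia (17 tested, 0 called, 3 over the list alone, median 0.225, adjusted p = 0.00492), reactive astrocytes (16 tested, 0 called, 0 over the list alone, median 0.14, adjusted p = 0.0323, Gfap 0.19) and lysosome genes (28 tested, 0 called, 3 over the list alone, median 0.0799, adjusted p = 0.042) also shifted upward. Downward shifts were of heat shock genes (20 tested, Hspb1 called at -0.80 with adjusted p = 0.0136, 7 lower over the list alone, median -0.186, adjusted p = 0.000297) and meninges (10 tested, 0 called, 0 of 10 above 0, median -0.587, adjusted p = 0.00262, highest member Ptgds -0.84). Oligodendrocyte precursors (13 tested, 1 called, 2 over the list alone, median -0.235, adjusted p = 0.00612) contained Gpr17, which fell from 10.0 ± 1.9 to 4.61 ± 0.566 FPKM (n = 3; log2 -0.96, adjusted p = 0.0477). Immediate early genes (21 tested, 0 called, 4 lower over the list alone, median -0.397, adjusted p = 0.00848, Egr1 -0.58) and collagen and extracellular matrix (18 tested, 3 lower, 2 higher and 5 lower over the list alone, median -0.191, adjusted p = 0.0405) shifted downward too, the latter with Col1a1 (-0.78, 0.0133), Serpinh1 (-0.67, 0.0134) and P4ha1, named after its value was seen (-0.37, 0.0495). Left-out libraries ended the camera call for lysosome (adjusted p = 0.442 without replicate 3 at 18 months, 0.176 without replicate 2 at 2 months), collagen (0.0892 and 0.0877 without the same libraries), immediate early genes (0.249 without replicate 1 at 18 months, 0.0888 without replicate 3 at 2 months), reactive astrocytes (0.0822 without replicate 2 at 18 months) and disease-associated microglia (0.0504 without replicate 3 at 18 months). Other alternatives ended it for lysosome (0.086 after removal of GC and length trends, 0.0917 with array weights, 0.0511 at a mean of at least 5 FPKM, 0.0706 without a filter) and collagen (0.12 after that removal, 0.062 with all 27 libraries in one fit, 0.0747 with array weights, 0.29 at a mean of at least 5 FPKM). They also ended it for reactive astrocytes (0.086 after that removal, 0.062 in one fit, 0.496 at a mean of at least 5 FPKM, 0.143 without a filter) and immediate early genes (0.0502 with array weights).

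Among cortex lists that camera did not call, complement had 2 members higher and 1 lower of 14 (3 and 1 over the list alone, median log2 0.179, adjusted p = 0.17, adjusted p = 0.779 with an estimated correlation), and was called without replicate 1 at 18 months (0.025). C1ra rose from 0.843 ± 0.369 to 2.73 ± 0.345 FPKM (n = 3; log2 1.03, adjusted p = 0.0472), and properdin (Cfp, named after its value was seen) fell (-0.42, 0.0498). The call of C1ra held under 7 of 11 alternatives and in 1 of 9 fits with a library left out. Cdkn1a was the only called member of the senescence list and fell from 10.06 ± 2.06 to 4.54 ± 0.593 FPKM (n = 3; log2 -0.98, adjusted p = 0.0414; list adjusted p = 0.874). Bdnf fell from 6.69 ± 0.612 to 3.90 ± 0.657 FPKM (n = 3; log2 -0.66, adjusted p = 0.0388) and Shank3 by less (-0.32, 0.0495), while the synapse list of 29 was not called (adjusted p = 0.526). Ribosomal proteins (73 tested, median 0.00169, mean -0.0438, camera upward with adjusted p = 0.626) held 1 call higher, Rpl10 (1.10, 0.0343), and 3 lower, Rpl26 (-0.58, 0.0186) and, named after their values were seen, Rps27 (-0.52, 0.0484) and Rpl31 (-0.61, 0.0498). Adjusted p was 0.365 for MHC class II, 0.422 for interferon response, 0.56 for cell division, 0.1 for nuclear oxidative phosphorylation, 0.788 for the circadian clock and 0.185 for neurogenesis. For cytokines the median was -0.0643, the mean 0.0615 and the camera direction downward (adjusted p = 0.874). Cell type markers gave 0.197 for microglia, 0.17 for astrocytes, 0.117 for oligodendrocytes, 0.327 for GABAergic interneurons, 0.1 for endothelium, 0.196 for mural cells, 0.601 for red blood cells, 0.264 for thalamus and 0.483 for dentate gyrus (adjusted p). Striatum markers lay above 0 in 10 of 10 genes (median log2 0.54, adjusted p = 0.1, Ppp1r1b 1.03), and choroid plexus markers had a median of -0.0315 with an upward camera direction (adjusted p = 0.98). Of adipocytes and of B and plasma cells 0 genes were tested, of T and NK cells 1.

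At 10 months cortex already carried the heart muscle transcripts and the low values of Tdg. The exonuclease gene Trex1, which clears stray DNA, was lower as well. Between 10 and 18 months the only called gene with a symbol was Ccdc36, a coiled-coil gene.

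The 10 against 2 month comparison asks what changes by mid-life and uses the same 2-month libraries. It called 292 genes in cortex, 114 higher and 178 lower. Myl2 (log2 2.66, adjusted p = 0.025), Mb (2.53, 0.0273) and Myl3 (2.19, 0.0361) rose most, and Tdg (-2.91, 6.69e-08), Trex1 (-1.25, 0.019) and Rpl37rt (-1.09, 0.0303) fell most among named genes. The count was 59, 128 and 49 without replicates 1, 2 and 3 at 10 months, 128 and 175 without replicates 2 and 3 at 18 months, and 83, 171 and 50 without replicates 1, 2 and 3 at 2 months. The Spearman correlation of a library's deviation with GC content was 0.347, 0.00611 and 0.186 in replicates 1, 2 and 3 at 2 months. At 10 months it was -0.329, -0.163 and -0.393. Removal of GC and length trends kept 179 of the 292 calls, with models without a symbol left out of that fit. Between 18 and 10 months 2 genes were called higher in cortex, Ccdc36 (1.18, 0.0121) and a model without a symbol. That count was 0 without replicate 2 or replicate 3 at 10 months, and 3 without replicate 2 at 18 months or replicate 1 or 2 at 2 months.

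In hippocampus the same small group of genes changed that also changed elsewhere: the calpain protease Capn11, the potassium channel Kcnh6 and the cold-inducible RNA-binding protein Rbm3 rose. Capg, an actin-capping protein of macrophages, and Bcl2a1b, a survival gene of myeloid cells, were called higher too, but most alternatives lost the call of Capg. Tdg, mirrored here too by that model, Srp9, the ribosomal protein gene Rpl34, the SCAN domain gene Scand1, the zinc finger gene Zfp804a and Adnp fell. Of all these genes, only Tdg, Capn11, Rbm3 and Rpl34 kept their calls in most fits with a library left out. Lists of microglia, complement and MHC genes shifted upward by camera while no member passed the test over all genes, and none of these list calls held with an estimated correlation. Markers of thalamus and striatum moved downward beside them without being called, and transcripts of hypothalamus and pituitary were high in some 2-month libraries.

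Of 13167 genes tested between 18 and 2 months in hippocampus, 40 were called, 23 higher and 17 lower, of which 17 were models without a symbol and 2 predicted genes. Among the genes tested, 443 were models without a symbol. Capn11 (gene 268958) rose from 10.98 ± 1.23 to 28.5 ± 4.69 FPKM (n = 3; log2 1.29, standard error 0.148, adjusted p = 0.0173). Rises were also called for Kcnh6 (0.97, 0.0377), Rbm3 (0.96, 0.0153), Capg (0.86, 0.034) and Bcl2a1b (0.81, 0.0174). Of 11 alternatives 3 kept the call of Capg and 7 that of Bcl2a1b, and of 9 left-out libraries 2 and 4. Tdg fell from 9.99 ± 2.28 to 0.713 ± 0.0929 FPKM (n = 3; log2 -2.66, adjusted p = 0.000259). Rpl34 (gene 68436) fell from 144 ± 19.2 to 79.6 ± 5.52 FPKM (n = 3; log2 -0.84, adjusted p = 0.02), and falls were called for Srp9 (-1.03, 0.0292), Scand1 (-0.79, 0.0368), Adnp (-0.70, 0.0279) and Zfp804a (-0.69, 0.0495, kept under 3 of 12 alternatives). The count was 26 without replicate 3 at 10 months, 11, 11 and 10 without replicates 1, 2 and 3 at 18 months, and 16 without replicate 3 at 2 months. Of the 12 named hippocampus genes that were called, only Tdg stayed called whichever library was left out. After removal of GC and length trends 6 genes were called higher and 11 lower, and 13 of the 40 main calls were kept. Models without a symbol were left out of that fit.

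Lists of microglia and macrophage genes had the smallest camera p in hippocampus with the preset correlation. With an estimated correlation 0 of 32 lists were called (smallest adjusted p = 0.2), and with the preset one 6 of the 10 splits of the libraries called at least the real 13 lists (up to 24). Beside them, thalamus and striatum markers each lay above 0 in 0 of 10 genes. Disease-associated microglia lay above 0 in 20 of 20 genes (0 called over all genes, 9 over the list alone, median log2 0.532, camera adjusted p = 8.71e-12). Macrophages and monocytes (10 tested, 0 called, 8 over the list alone, median 0.603, adjusted p = 3.84e-11, Csf1r 0.47), microglia (13 tested, 0 called, 6 over the list alone, median 0.303, adjusted p = 2.65e-08) and MHC class I and antigen processing (13 tested, 0 called, 6 over the list alone, median 0.467, adjusted p = 2.65e-08) shifted upward. Complement (14 tested, 0 called, 5 over the list alone, median 0.429, adjusted p = 0.000121) had C1qa at 35.2 ± 4.4 FPKM at 2 months and 53.3 ± 4.58 FPKM at 18 months (n = 3; log2 0.59, adjusted p = 0.123, or 0.0065 over the list alone). Reactive astrocytes (19 tested, 0 called, 3 over the list alone, median 0.374, adjusted p = 1.4e-07, Gfap 1.03 with adjusted p = 0.441), lysosome (28 tested, 0 called, 4 over the list alone, median 0.17, adjusted p = 9.41e-07), MHC class II (6 tested, 0 called, 0 over the list alone, median 0.81, adjusted p = 0.00055, Cd74 1.05), cytokines (8 tested, 0 called, 2 over the list alone, median 0.276, adjusted p = 0.00213) and meninges (10 tested, 0 called, median 0.77, adjusted p = 0.00839) shifted upward too. Heat shock genes (20 tested, 0 called, 2 lower over the list alone, median -0.316, adjusted p = 8.5e-06), oligodendrocyte precursors (13 tested, 0 called, median -0.216, adjusted p = 0.00974) and neurogenesis (16 tested, 0 called, median -0.314, adjusted p = 0.0246) shifted downward. Calls ended for meninges without replicate 2 at 18 months (0.225) or replicate 2 at 2 months (0.456), for neurogenesis without replicate 2 at 2 months (0.162) and for oligodendrocyte precursors without replicate 2 at 18 months (0.0694). Array weights ended the calls of complement (0.236), MHC class II (0.423), cytokines (0.104), reactive astrocytes (0.076), neurogenesis (0.103) and oligodendrocyte precursors (0.0511) and turned that of meninges (0.227). A mean of at least 5 FPKM ended those of cytokines (0.11) and neurogenesis (0.218).

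Other hippocampus lists were not called. Thalamus markers lay above 0 in 0 of 10 genes (median log2 -0.732, adjusted p = 0.0539) and striatum markers in 0 of 10 (median -0.598, adjusted p = 0.115). Adjusted p was 0.0699 for dentate gyrus, 0.795 for interferon response, 0.472 for senescence, 0.935 for cell division, 0.248 for collagen, 0.181 for oxidative phosphorylation, 0.882 for immediate early genes and 0.472 for synapse. It was 0.739 for mural cells, 0.115 for red blood cells, 0.354 for astrocytes, 0.148 for oligodendrocytes and 0.221 for GABAergic interneurons. Medians, means and camera direction differed in sign for ribosomal proteins (73 tested, 1 lower, median 0.00818, mean -0.051, upward, adjusted p = 0.534), the circadian clock (mean -0.00284, upward, 0.739), endothelium (median -0.0259, upward, 0.739) and choroid plexus (mean -0.0526, upward, 0.861).

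By 10 months in hippocampus Capn11 and Kcnh6 had risen, together with Pcdhga12, a protocadherin of neuronal contacts. Srp9, Rpl34 and the values of Tdg had fallen. No gene with a symbol was called between 18 and 10 months.

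The 10 against 2 month comparison, on the same 2-month libraries, called 57 genes in hippocampus, 22 higher and 35 lower. Capn11 (log2 1.22, adjusted p = 0.0201), Pcdhga12 (1.05, 0.0104) and Kcnh6 (0.91, 0.0435) rose most among named genes, with 8 models or predicted genes above the smallest of these rises, and Tdg (-2.74, 0.000202), Srp9 (-1.26, 0.012) and Rpl34 (-1.22, 0.0023) fell most, with 3 such models below the smallest of these falls. The count was 14, 20 and 15 without replicates 1, 2 and 3 at 10 months, 33, 30 and 20 without replicates 1, 2 and 3 at 18 months, and 28 and 30 without replicates 1 and 3 at 2 months. With median-ratio scaling 43 were called higher and 32 lower, and with quantile normalisation 35 and 32. Between 18 and 10 months 1 model without a symbol was called higher, and 2 genes without replicate 2 at 18 months or replicate 1 or 3 at 2 months.

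Kidney had many calls, mostly rises in the values as scaled by the submitters. The protease inhibitors Serpina1a and Slpi, the squamous gene Sprr1a, the pyrimidine-degrading enzyme Dpys, the selenium-binding protein Selenbp2 and the monocyte-attracting chemokine Ccl8 rose most among named genes. Complement genes rose, C3 and C4b and C1qb and C1qa of the complex that starts the classical pathway, C1qa only without removal of GC and length trends. Klotho (Kl), the kidney co-receptor of a phosphate-regulating hormone, the podocyte factor Wt1 and the replicative helicase Mcm6 fell. The call of Wt1 was lost when most single libraries were left out. The injury genes Fgg and Krt18 and the macrophage genes Itgam and Cd68 rose, Krt18 and Cd68 again only without that removal. The call of Itgam was lost with median-ratio scaling, a common FPKM sum, the replicate block and a minimum fold change of 2.

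Of 12451 genes tested between 18 and 2 months in kidney, 338 were called, 291 higher and 47 lower, of which 49 were models without a symbol and 10 predicted genes. Among the genes tested, 425 were models without a symbol. Serpina1a rose from 4.09 ± 2.17 to 45.1 ± 11.9 FPKM (n = 3; log2 3.22, adjusted p = 0.00915), Selenbp2 (gene 20342) from 16.9 ± 2.05 to 103.1 ± 24.8 FPKM (n = 3; log2 2.52, standard error 0.191, adjusted p = 0.000374) and Ccl8 from 0.233 ± 0.176 to 6.24 ± 2.74 FPKM (n = 3; log2 2.49, adjusted p = 0.00376). Rises were also called for Sprr1a (2.70, 0.0211), Dpys (2.60, 0.0285) and Slpi (2.39, 0.0436), the last kept under only 4 of 12 alternatives. Tdg fell from 7.37 ± 0.864 to 0.337 ± 0.0379 FPKM (n = 3; log2 -2.64, adjusted p = 2.64e-06) and Mcm6 (gene 17219) from 4.34 ± 1.1 to 0.97 ± 0.217 FPKM (n = 3; log2 -1.43, adjusted p = 0.00422). Further falls were of Mafg (-1.57, 0.0254), the transporter Slc16a14 (-1.34, 0.0427), the zinc finger gene Zfp874a (-1.24, 0.023) and the kinase Camk1g (-1.23, 0.00915). The call of Slc16a14 held under 6 of 12 alternatives and in 2 of 9 fits with a library left out. The count was 198 and 154 without replicates 2 and 3 at 10 months, 181 and 194 without replicates 2 and 3 at 18 months, and 152, 193 and 84 without replicates 1, 2 and 3 at 2 months, and 16 of 37 named and called kidney genes stayed called whichever library was left out, among them C4b, C1qa, C1qb, Ccl8, Igfbp2, Kl, Laptm5, Mcm6, Selenbp2, Serpina1a and Tdg. The median log2 change of all genes was 0.0609, and the preponderance of rises depended on scaling: 165 higher and 56 lower with median-ratio scaling, 228 and 113 with quantile normalisation, 144 and 168 after removal of GC and length trends. Of the 338 calls, 207 were kept with median-ratio scaling, 245 with quantile normalisation and 140 after that removal, which leaves out models without a symbol. Kidney had more calls than cortex here (338 against 238), but fewer with a common FPKM sum (240 against 266), median-ratio scaling (221 against 262), the replicate block (124 against 179), a minimum mean of 5 FPKM (134 against 140) and removal of GC and length trends (312 against 330), and fewer than hippocampus with array weights (1282 against 2248).

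Complement in kidney (20 tested, 6 higher, 10 over the list alone, median log2 0.585, camera adjusted p = 0.000167, adjusted p = 0.4 with an estimated correlation) shifted upward with the preset correlation only. With an estimated correlation 0 lists were called in kidney (smallest adjusted p = 0.4), and with the preset one 3 of the 10 splits of the libraries called at least the real 13 lists (up to 17). The complement list held C3 (gene 12266), from 9.15 ± 4.14 to 42.3 ± 13.1 FPKM (n = 3; log2 2.14, adjusted p = 0.0181), C1qb, from 16.9 ± 3.53 to 41.1 ± 7.48 FPKM (n = 3; log2 1.24, adjusted p = 0.0104), and C1qa, from 20.6 ± 4.45 to 45.2 ± 6.45 FPKM (n = 3; log2 1.11, adjusted p = 0.0138). After removal of GC and length trends the calls of C1qa (adjusted p = 0.0545), Cd68 (0.0537), Fcgr3 (0.0516), Krt18 (0.0537) and Il34 were lost, while C3 (0.0307) and C1qb (0.0481) kept theirs. Those of Slpi, Cd79b, Cdkn2c, Per3, Ifitm3 and Nbl1 were lost too, 26 of 37 named and called kidney genes keeping theirs. The GC trend of the kidney libraries (Spearman correlation of a library's deviation with GC content) differed between ages without following their order, at 0.707, 0.0816 and 0.111 in replicates 1, 2 and 3 at 18 months, -0.257, -0.0403 and -0.21 at 2 months and -0.479, -0.314 and -0.416 at 10 months. Cytokines and chemokines (18 tested, 5 higher, 12 over the list alone, median 0.535, adjusted p = 5.86e-06) held Ccl8 and Il34 (1.11, 0.0342) and, named after their values were seen, Cxcl10 (1.06, 0.0381), Cxcl13 (1.78, 0.048) and Ccl6 (0.90, 0.0422). Macrophages and monocytes (16 tested, 4 higher, 9 over the list alone, median 0.629, adjusted p = 9.75e-05) held Fcgr3 (0.96, 0.0165) and Itgam (0.88, 0.0386). The call of Itgam held under 7 of 11 alternatives and in 2 of 7 fits with a library left out. MHC class I lay above 0 in 14 of 14 genes (0 called, 10 over the list alone, median 0.506, adjusted p = 4.67e-05, B2m 0.49), and MHC class II (8 tested, 0 called, 7 over the list alone, median 0.801, adjusted p = 0.000252, Cd74 0.89) and T and NK cells (5 tested, 0 called, 4 over the list alone, median 0.675, adjusted p = 0.00656) shifted upward. Lysosome genes (28 tested, 2 higher, 6 over the list alone, median 0.195, adjusted p = 0.00656) held Laptm5 (1.18, 0.011) and Cd68 (1.20, 0.0141). Tubular injury (20 tested, 3 higher and 1 lower, 8 and 1 over the list alone, median 0.465, adjusted p = 0.00847) held Fgg (1.496, 0.02) and Krt18 (0.86, 0.0211). Ribosomal proteins (73 tested, 0 called, 0 over the list alone, median 0.258, adjusted p = 0.00128, Rpl41 0.53) shifted upward.

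Downward shifts in kidney, likewise with the preset correlation only, were of heat shock genes (20 tested, 0 called, 4 lower over the list alone, median log2 -0.285, camera adjusted p = 2.25e-06, Hspa8 -0.53), podocytes and glomerulus (11 tested, 1 lower, median -0.282, adjusted p = 0.000777, Wt1 -0.71 with adjusted p = 0.0399), renin-angiotensin and ion transport regulators (15 tested, 1 lower, median -0.244, adjusted p = 0.00656) and proximal tubule (20 tested, 0 called, 3 lower over the list alone, median -0.221, adjusted p = 0.0206). Kl (gene 16591) fell from 163.7 ± 6.86 to 87.5 ± 6.51 FPKM (n = 3; log2 -0.90, adjusted p = 0.00718). The call of Wt1 held under 8 of 11 alternatives and in 2 of 9 fits with a library left out. Calls ended for proximal tubule without replicate 2 at 18 months (0.497) or replicate 1 at 2 months (0.0594), for T and NK cells without replicate 3 at 18 months (0.101) and for ribosomal proteins without replicate 2 at 2 months (0.052). Removal of GC and length trends ended the calls of ribosomal proteins (0.296) and proximal tubule (0.115). The latter also ended with median-ratio scaling (0.057), quantile normalisation (0.0545) and array weights (0.0818), and a mean of at least 5 FPKM ended that of macrophages and monocytes (0.139). Not called in the main analysis by camera were B and plasma cells (7 tested, 1 higher, 5 over the list alone, median 0.964, adjusted p = 0.0508, but called under 9 alternatives), whose member Cd79b rose (1.27, 0.0473), senescence (14 tested, 2 higher, adjusted p = 0.106) with rises of Igfbp2 (1.70, 0.00658) and Cdkn2c (0.61, 0.0381), the circadian clock (17 tested, 2 higher, adjusted p = 0.319) with rises of Cry2 (0.87, 0.0302) and Per3 (1.00, 0.0431, kept under 3 of 11 alternatives), and interferon response (25 tested, 1 higher, adjusted p = 0.468) with a rise of Ifitm3 (0.51, 0.0459, kept under 4 of 12). Adjusted p was 0.109 for oxidative phosphorylation, 0.882 for immediate early genes, 0.882 for androgen-dependent genes (Kap -0.33), 0.0869 for mural cells, 0.747 for red blood cells, 0.345 for adipocytes and 0.142 for loop, distal tubule and collecting duct. Signs differed for cell division (5 tested, median 0.244, mean -0.0893, downward, 0.882), collagen (median 0.0867, mean 0.0853, downward, 0.908), fatty acid oxidation (median 0.0236, mean 0.121, downward, 0.882) and endothelium (median 0.0539, downward, 0.509). Of adrenal gland markers 1 gene was tested.

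By 10 months in kidney Selenbp2 and Igfbp2, a binding protein of insulin-like growth factors, had risen, and Mcm6, the mitochondrial carrier Slc25a25 and the values of Tdg had fallen. The complement and macrophage genes were not among the largest changes at that age. No gene was called between 10 and 18 months, except under some alternative models.

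The 10 against 2 month comparison, on the same 2-month libraries, called 55 genes in kidney, 40 higher and 15 lower. Selenbp2 (log2 2.28, adjusted p = 0.00062) and Igfbp2 (1.44, 0.0242) rose, and Tdg (-2.76, 1.76e-06), Mcm6 (-1.73, 0.00113) and Slc25a25 (-1.46, 0.034) fell. The count was 26 and 23 without replicates 1 and 3 at 10 months, and 32 and 23 without replicates 2 and 3 at 2 months. With quantile normalisation 26 were called higher and 20 lower, and after removal of GC and length trends 38 and 51. That removal, without the models that have no symbol, kept 27 of the 55. Between 18 and 10 months limma called 0 genes in kidney, with 2202 at an unadjusted p below 0.05 and a smallest adjusted p of 0.167. The smallest p values there belonged to the lipase anchor Gpihbp1 (0.66), the myeloid gene Lrrc25 (0.88) and the NF-kB subunit Relb (0.69), each with adjusted p = 0.167. Without replicate 1 at 10 months 4 genes were called, and without replicate 2 at 18 months 1, while array weights called 30 and all 27 libraries in one fit 1002.

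**Figure D2:**
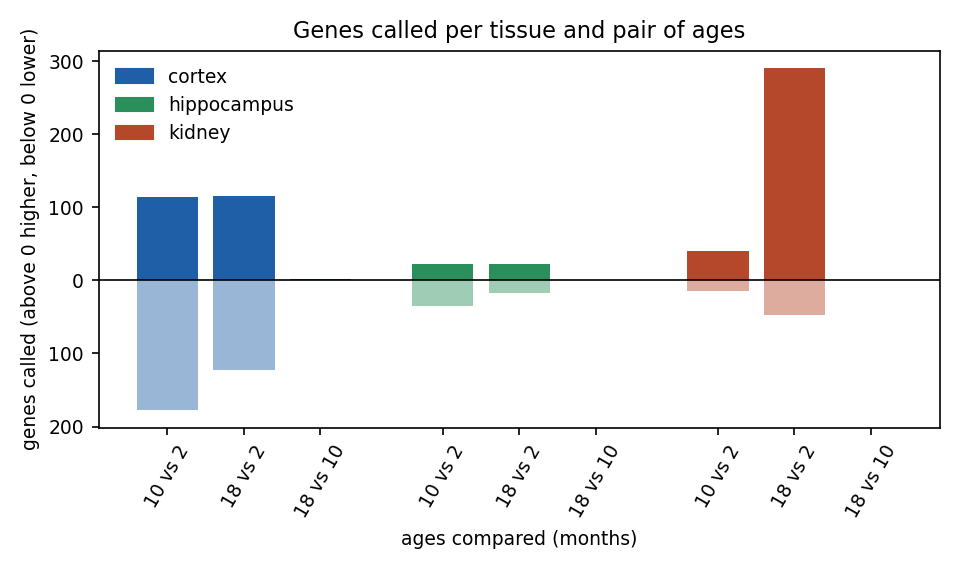
Genes called higher (above 0) and lower (below 0, paler) in each tissue for 18 against 2, 10 against 2 and 18 against 10 months.

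In the main fits, differences between tissues were called only for kidney against the brain regions, and few of these calls remained without some single animals. The retinoid enzyme gene Aldh1a1 and the membrane protein gene Tmem158 changed more in kidney than in cortex, and Tmem158 and the branched-chain aminotransferase Bcat1 more than in hippocampus. Against hippocampus, the calls of Tmem158 and Bcat1 each held in only 2 of 9 fits with an animal left out. Alas1, the first enzyme of heme synthesis, moved downward in kidney relative to both brain regions. Cortex stood apart from kidney in the heart genes Myl2 and phospholamban (Pln), but the call of Pln held in only 1 of 9 fits with an animal left out. Nbl1, an antagonist of bone morphogenetic proteins, was called higher in kidney and lower in cortex, but most alternatives lost each of these calls.

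The interaction test asks whether the 18 against 2 month change differs between tissues. Its model over all 27 libraries has no term for the animal, although the tissues come from the same animals. With the animal as a block it called 2 genes for hippocampus minus cortex, 67 for kidney minus cortex and 25 for kidney minus hippocampus, against 0, 65 and 17 without it. The blocked model kept 42 of the 65 and 14 of the 17. For kidney minus cortex 65 of 10755 genes were called, 55 positive and 10 negative. Aldh1a1 differed by log2 2.59 (adjusted p = 0.0251; kidney 2.24, cortex -0.35) and Tmem158 by 2.43 (0.0251; 1.96 and -0.48). Kidney Aldh1a1 was at 5.97 ± 5.87 FPKM at 2 months and kidney Tmem158 at 8 ± 6.07 FPKM at 18 months (n = 3), with SDs near the means. Myl2 differed by -2.75 (0.0179; kidney 0.77, cortex 3.52), Pln by -1.495 (0.045; -0.18 and 1.31) and Alas1 by -0.95 (0.00704; -0.77 and 0.18). That count was 6, 23 and 29 without animals 1, 2 and 3 at 18 months, and 27, 105 and 4 without animals 1, 2 and 3 at 2 months. It was 27 positive and 10 negative with median-ratio scaling, and 37 and 40 with quantile normalisation. For kidney minus hippocampus 17 of 10902 genes were called, 12 positive and 5 negative, with Tmem158 at 2.45 (0.0414; hippocampus -0.50), Bcat1 at 2.42 (0.0414; kidney 2.01, hippocampus -0.41), the nucleotidase Nt5e at -1.13 (0.0496; -0.91 and 0.22), Alas1 at -1.01 (0.00261; hippocampus 0.24) and the adducin Add3 at -0.76 (0.0204; -0.46 and 0.30). The call of Nt5e was lost with the animal as a block (adjusted p = 0.102). Those of Tmem158, Bcat1 and Nt5e held under 8, 7 and 5 of 11 alternatives. Each held in 2 of 9 fits with an animal left out. This count was 2 and 6 without animals 1 and 2 at 18 months, and 9 without animal 1 at 2 months. It was 7 positive and 7 negative with median-ratio scaling, 2 and 6 with quantile normalisation and 0 and 3 at a mean of at least 5 FPKM. For hippocampus minus cortex limma called 0 of 12705 genes, with 373 at an unadjusted p below 0.05. Myl2 (-2.94, adjusted p = 0.13), Mb (-2.55, 0.179) and Zfp804a (-0.62, 0.948) had the smallest p. The count there was 1 without animal 3 at 10 months, 2 without animal 3 at 18 months and 1 without animal 1 at 2 months. Only Nbl1 was called in opposite directions, at log2 0.83 in kidney (adjusted p = 0.0484) and -0.53 in cortex (0.0457), and these calls held under 3 and 5 of 12 alternatives. Its kidney call was lost whichever library was left out, as were those of Shank3 in cortex (held under 4 of 12) and Ifitm3 in kidney. The cortex call of Mafg held under 5 of 11.

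A small set of genes changed in the same direction in all 3 tissues. Capn11, Kcnh6, Rbm3 and Pld4, an endolysosomal nuclease of myeloid cells, rose everywhere, and Srp9 and the values of the DNA repair gene Tdg fell everywhere. The calls of Pld4 in cortex and hippocampus, and of Kcnh6 and Srp9 in hippocampus, were lost when most single libraries were left out. A model without a symbol rose where Tdg fell, so a change of the gene itself is not settled. C4b was not in this set because its adjusted p in hippocampus did not pass, although its unadjusted p there was near that in cortex.

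Overlap between tissues asks which changes are shared. The tissues come from the same animals and are not independent. All 3 tissues shared 12 genes called higher (0.00274 expected by chance) and 5 called lower (0.000358 expected) at 18 against 2 months, 17 in all, of which 10 were models without a symbol. In cortex, hippocampus and kidney the log2 change was -2.85, -2.66 and -2.64 for Tdg, 1.16, 1.29 and 1.37 for Capn11, 0.87, 0.96 and 1.26 for Rbm3, 0.74, 0.97 and 1.09 for Kcnh6, 0.47, 0.66 and 1.11 for Pld4, and -1.07, -1.03 and -1.05 for Srp9. The call of Pld4 held under 5 of 11 alternatives in hippocampus and 6 of 11 in cortex, and in 1 of 9 fits with a library left out in each. That of Kcnh6 in hippocampus held under 8 of 12 alternatives and in 1 of 9 such fits. A model without a symbol, in the same set, went opposite to Tdg, from 0.0467 ± 0.0451 to 9.80 ± 0.442 FPKM in cortex, from 0.02 ± 0.0265 to 9.31 ± 0.671 in hippocampus and from 0.06 ± 0.05 to 6.86 ± 0.639 in kidney (n = 3). Another such model in the set went opposite to Kcnh6. Its means fell from 30.57 to 2.92 FPKM in cortex, 33.25 to 2.23 in hippocampus and 53.28 to 4.55 in kidney (n = 3). That model mirrored Kcnh6 best in cortex, but other models did so in hippocampus and kidney. The count of 17 was 7, 8 and 7 without animals 1, 2 and 3 at 18 months and 11 without animal 3 at 2 months. Hippocampus and cortex shared 16 higher (0.184 expected, one-sided Fisher exact p = 1.21e-29) and 12 lower (0.152 expected, exact p = 5.62e-22). Those 28 were 18 without animal 3 at 10 months, 8, 9 and 8 without animals 1, 2 and 3 at 18 months, and 14 without animal 3 at 2 months. Kidney and cortex shared 28 higher (1.5 expected, exact p = 8.6e-29) and 8 lower (0.292 expected, exact p = 3.12e-10). Those 36 were 23 and 21 without animals 1 and 3 at 10 months, 17, 15 and 15 without animals 1, 2 and 3 at 18 months, and 18 and 13 without animals 2 and 3 at 2 months. Kidney and hippocampus shared 14 higher (0.405 expected, exact p = 6.48e-20) and 5 lower (0.0394 expected, exact p = 2.34e-10). Those 19 were 7, 8 and 7 without animals 1, 2 and 3 at 18 months and 11 without animal 3 at 2 months. In hippocampus and cortex, 11 of the 16 higher and 4 of the 12 lower were models without a symbol. Such models were 11 of the 28 and 3 of the 8 in kidney and cortex. In kidney and hippocampus they were 7 of the 14 and 3 of the 5. Of the genes tested in both tissues they were 404 of 12705, 214 of 10755 and 214 of 10902, in the same order.

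**Figure D3:**
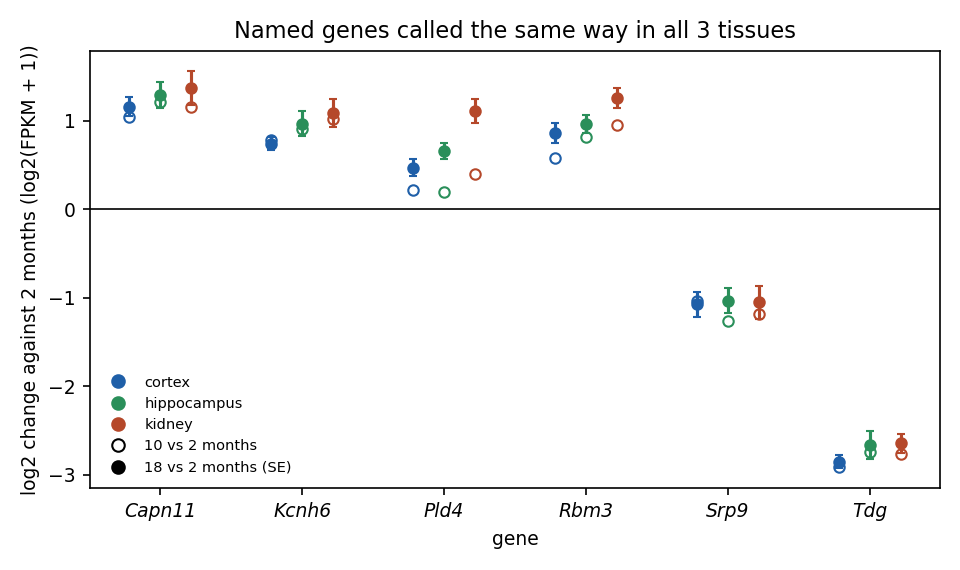
Log2 change of named genes that were called in the same direction in all 3 tissues, at 10 against 2 months (open, without error bar) and 18 against 2 months (filled, with standard error).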

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

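The tests of the shared genes, of Rpl29 and of the heart muscle transcripts were chosen only after those results were seen, and the counts under splits of the libraries were chosen before.

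The 17 genes called in the same direction in all 3 tissues had mostly reached their 18-month level by 10 months. A steady progress with age would put the share of the change reached at 10 months near 0.5, and the median share was 0.98 (quartiles 0.892 and 1.03), with Pld4 at 0.366. A GC content or transcript length trend of the libraries is unlikely to explain the 7 with a symbol, because the median ratio of the change after to before its removal was 0.998 (quartiles 0.993 and 1.03), with 5 of these 7 still called in all 3 tissues, while the 10 without a symbol could not be tested. Reads assigned to another gene model may explain 3 of the 17, Tdg and 2 models without a symbol (Tdg and 1 of these mirror each other, and the mirror of the other is also among the 17), whose values are mirrored by the same other model in every tissue (in cortex Tdg went from 11.95 to 0.797 FPKM and its mirror from 0.0467 to 9.80), and leave the other genes open. A fixed difference between the 2-month animals or libraries and the older ones remains possible, since both comparisons with 2 months use the same 2-month libraries. Of the 17, 0 were called at 18 against 10 months. This count cannot decide the question, because only 2, 1 and 0 genes were called there in cortex, hippocampus and kidney.

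Rpl29 (gene 19944) differed between animals of one age alike in all 3 tissues, for example 3.05, 151.33 and 3.77 FPKM in replicates 1, 2 and 3 of cortex at 18 months. For noise of single libraries as a cause, 99.3% of the within-age variance lay between animals, against a median of 33.1% and a highest of 99.44% over 46656 arrangements of the animals (45 as large, exact permutation p = 0.000965). Rpl29 was picked out for this same pattern. The p makes no allowance for that choice among genes and does not by itself exclude noise. The first bound set for that test, that no other arrangement be as large, was not met, and it was replaced by the permutation p after the result was seen. Reads assigned to another gene model, one without a symbol, are consistent with the values, as the SD of their sum was at most 0.445 of that of Rpl29 in hippocampus and kidney. A variant carried by some animals is also consistent with them, since Rpl29 made up within 0.1 of 0, 0.5 or 1 of that sum in 27 of 27 libraries, which would mean that the animals were not genetically uniform at this gene.

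Heart muscle transcripts were higher in cortex at 18 than at 2 months. RNA of heart muscle in the cortex libraries is possible but was not settled, as 23 of 33 heart genes, a list chosen after the values were seen, were separated upward (5% expected by chance), 4 of the 10 with a mean of at least 1 FPKM at 2 months and 19 of the others, with 10 called and a median log2 change of 0.836 (SD 1.04). RNA of skeletal muscle is unlikely, with 0 of 8 genes separated and a median of 0.0293 (SD 0.0983). A change of the brain itself with age remains open, with a median log2 change of the heart list of 0.104 in hippocampus and 11 genes separated upward in hippocampus and 12 in kidney. The route by which such RNA could enter was not tested.

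The change from 2 to 18 months differed between tissues for some genes. For kidney minus cortex 65 genes were called. Aldh1a1 differed by log2 2.59. Tmem158 differed by 2.43. Myl2 differed by -2.75. Pln differed by -1.495, and its call was lost without the 2 libraries that stood apart. It was also lost after removal of GC and length trends, with median-ratio scaling and with a common FPKM sum. Alas1 differed by -0.95. For kidney minus hippocampus 17 genes were called. Tmem158 differed by 2.45, Bcat1 by 2.42 and Nt5e by -1.13, all lost without the 2 libraries that stood apart, Nt5e also with the animal as a block. Alas1 differed by -1.01 and Add3 by -0.76.

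Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few to reach a share under 0.05. The real split called 238 genes in cortex at 18 against 2 months (highest other split 1), 292 at 10 against 2 months (0), 40 and 57 in hippocampus (0 and 0), and 338 and 55 in kidney (2 and 0). In each of these the real split was the 1 split with as many calls. At 18 against 10 months cortex had 2 calls in 2 splits, hippocampus 1 call in 1 split, and kidney 0 calls with up to 2 in the other splits, so that all 10 splits called as many. For differences between tissues the real split called 0 for hippocampus minus cortex (up to 3 in others, as many in all 10), 65 for kidney minus cortex (0) and 17 for kidney minus hippocampus (1). Overlaps were 17, 28, 36 and 19 for all 3 tissues, hippocampus with cortex, kidney with cortex and kidney with hippocampus, each with 0 in every other split. Lists were different: 6 of 10 splits in cortex called at least the real 10 (up to 16), 6 in hippocampus at least the real 13 (up to 24) and 3 in kidney at least the real 13 (up to 17), so camera calls of lists with the preset correlation can follow the structure of the samples, in cortex and hippocampus in more than 5 of 10 splits.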

How the results depend on the processing

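Removal of GC and length trends, genes with a symbol only, and leaving out the 2 libraries that stood apart were chosen only after the results were seen. Group sizes of 3 make every count depend on single libraries, the tissues share animals, depth is unknown, and all comparisons with 2 months share the 2-month libraries. Counts below are genes called, in the order 18 against 2, 10 against 2 and 18 against 10 months where several are given, and the main counts are 238, 292 and 2 in cortex, 40, 57 and 1 in hippocampus and 338, 55 and 0 in kidney. Differences between tissues had 0 (hippocampus minus cortex), 65 (kidney minus cortex) and 17 (kidney minus hippocampus) genes. Overlaps had 17 genes in all 3 tissues, 28 in hippocampus and cortex, 36 in kidney and cortex and 19 in kidney and hippocampus. Where a value moved, the cause was not tested.

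Array weights raised the counts to 1020 and 1045 in cortex, 2248, 1552 and 7 in hippocampus and 1282, 173 and 30 in kidney. Differences between tissues became 12, 429 and 192, and overlaps 152, 506, 191 and 374. All 27 libraries in one fit gave 218, 1177 and 4 in hippocampus, 2365, 704 and 1002 in kidney, and overlaps of 43, 85, 78 and 92.

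A fold of at least 2 left 46 and 44 genes in cortex, 21 and 21 in hippocampus, 114 and 36 in kidney, 20 for kidney minus cortex, 11 for kidney minus hippocampus, and overlaps of 17 (hippocampus and cortex), 15 (kidney and cortex) and 12 (kidney and hippocampus). A mean FPKM of at least 5 left 140 genes in cortex at 18 against 2 months and 1 at 18 against 10 months, 20 in hippocampus at 18 against 2 months, 134 and 27 in kidney, 20 for kidney minus cortex, 3 for kidney minus hippocampus, and overlaps of 8, 15, 17 and 9. No filter on low values gave 178 in cortex at 10 against 2 months and 0 at 18 against 10 months, 3 in hippocampus at 18 against 10 months, and differences of 2, 460 and 279. Genes with a symbol only gave 139 in cortex and 1 at 18 against 10 months, 8, 24 and 0 in hippocampus, 13 in kidney at 10 against 2 months, 6 for kidney minus hippocampus, and overlaps of 4, 5, 13 and 4.

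Within a tissue the replicate block joins animals of different ages that carry the same number, which the values did not pair across ages, and for differences between tissues the block is the animal. It gave 149 in cortex at 10 against 2 months, 17 and 20 in hippocampus, 124 and 35 in kidney, 2 for hippocampus minus cortex (67 and 25 for the other differences), and overlaps of 9, 15, 18 and 10. Under the replicate block camera also called B and plasma cells in kidney (adjusted p = 0.0357), dentate gyrus (0.0387), red blood cells (0.00461) and thalamus (0.0295) in hippocampus, and oligodendrocytes (0.0344) and striatum (0.0188) in cortex, and lost none.

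After removal of GC and length trends 1 gene was called in cortex at 18 against 10 months, 17 and 0 in hippocampus at 18 against 2 and 18 against 10 months, 89 in kidney at 10 against 2 months, 23 for kidney minus cortex, and overlaps were 8 (all 3 tissues), 15 (hippocampus and cortex) and 9 (kidney and hippocampus). Median ratio scaling gave 221 in kidney at 18 against 2 months and 37 for kidney minus cortex. Scaling to a common sum per library (TPM) gave 26 for kidney minus cortex. For kidney minus hippocampus, pseudocount 0.1 gave 27, quantile normalisation 8 and leaving out the 2 libraries that stood apart 6. Camera with an estimated correlation called 0 lists in cortex, 0 in hippocampus and 0 in kidney, against 10, 13 and 13.

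Camera also called lists that were not called in the main analysis. B and plasma cells in kidney were called after removal of GC and length trends (adjusted p = 0.0213), with all 27 libraries in one fit (0.00563), array weights (0.0224), median ratio scaling (0.0211), no filter (0.0177), pseudocount 0.1 (0.0481), quantile normalisation (0.0407), the replicate block (0.0357) and a common FPKM sum (0.0213). Thalamus in hippocampus was called after removal of GC and length trends (0.035), with one fit (0.00254), median ratio scaling (0.0243), no filter (0.0224), quantile normalisation (0.033), the replicate block (0.0295) and a common FPKM sum (0.0448). In cortex, astrocytes were called with array weights (0.0171). Oligodendrocytes and striatum were called there in one fit (0.0484 each) and with the block (0.0344 and 0.0188). In hippocampus, dentate gyrus was called in one fit (0.0179) and with the block (0.0387), and red blood cells with the block (0.00461) and no filter (0.0423). Array weights called mural cells (0.0249) and ribosomal proteins (0.031) there. No filter called cell division (0.00366), oxidative phosphorylation (0.0395) and striatum (0.043). In kidney, a mean of at least 5 FPKM called the circadian clock (0.0113). Array weights called loop and distal tubule (0.0168) and senescence (0.0307), which no filter called too (0.046).

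Leaving out 1 library made 51 list values called and ended 16. In cortex it called oligodendrocytes (0.0405 without replicate 1 at 18 months, 0.0111 and 0.0294 without replicates 1 and 3 at 2 months). It called striatum (0.0427 and 0.0492 without replicates 1 and 3 at 10 months, 0.025 and 0.0126 without replicates 1 and 2 at 18 months). It called endothelium (0.0126 without replicate 2 at 18 months, 0.0122 without replicate 2 at 2 months) and oxidative phosphorylation (0.025 and 0.0125 without replicates 1 and 2 at 18 months, 0.0171 without replicate 1 at 2 months). Astrocytes (0.0144) and mural cells (0.0317) were called without replicate 2 at 2 months, complement (0.025) without replicate 1 at 18 months. In hippocampus it called thalamus without 5 different libraries (0.00397 to 0.0375) and dentate gyrus (0.00143 to 0.037) and oligodendrocytes (0.0087 to 0.026) without 3 each. Striatum (0.00991 and 0.0201), red blood cells (0.00591 and 0.0447) and collagen (0.00445 and 0.0378) were called there without 2 each. Without 1 each it called synapse (0.00953), choroid plexus (0.0388), ribosomal proteins (0.00548), immediate early genes (0.0357), interferon response (0.0484), astrocytes (0.0445) and oxidative phosphorylation (0.047). In kidney it called B and plasma cells without replicate 2 at 10, 18 or 2 months (0.0428, 0.00552 and 0.0191) and oxidative phosphorylation without 3 libraries (0.00844 to 0.04). Without 1 each it called interferon response (0.00128), mural cells (0.00782), loop and distal tubule (0.0192), red blood cells (0.0348), senescence (0.0453) and endothelium (0.0471).

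C4b in cortex (log2 1.32, adjusted p = 0.0495) was not called with genes with a symbol only (log2 1.32, adjusted p = 0.0565), no filter (1.32, 0.0758), pseudocount 0.1 (1.46, 0.0566) or the replicate block (1.32, 0.0732). C4b in hippocampus was called with all 27 libraries in one fit (1.62, 0.00594) and array weights (1.86, 0.0025). C4b in kidney was called under every alternative in which it was tested, and was not tested at a mean FPKM of at least 5. Lists turned direction in 5 values, with unadjusted camera values of 4.76e-05 for cell division and 0.0115 for cytokines in cortex without a filter (adjusted p = 0.000333 and 0.0403), and with array weights in hippocampus 0.000761 for choroid plexus, 0.00416 for interferon response and 0.142 for meninges (adjusted p = 0.00348, 0.0166 and 0.227).

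Leaving out 1 library, counts in cortex ranged from 52 (replicate 1 at 18 months) to 277 (replicate 2 at 10 months) at 18 against 2 months, from 49 (replicate 3 at 10 months) to 283 (replicate 1 at 18 months) at 10 against 2 months, and from 0 to 3 at 18 against 10 months. In hippocampus they ranged from 10 (replicate 3 at 18 months) to 59 (replicate 2 at 2 months), from 14 (replicate 1 at 10 months) to 68 (replicate 2 at 2 months) and from 1 to 2. In kidney they ranged from 84 (replicate 3 at 2 months) to 396 (replicate 1 at 10 months), from 23 (replicate 3 at 10 months or at 2 months) to 82 (replicate 1 at 18 months) and from 0 to 4. Differences between tissues ranged from 0 to 2, from 4 (animal 3 at 2 months) to 105 (animal 2 at 2 months) and from 2 (animal 1 at 18 months) to 21 (animal 1 at 10 months). Overlaps ranged from 7 to 16 in all 3 tissues, from 8 to 37 in hippocampus and cortex, from 13 to 27 in kidney and cortex and from 7 to 21 in kidney and hippocampus. C4b in cortex ranged from 0.98 (replicate 3 at 2 months, adjusted p = 0.0792) to 1.54. Lists turned direction for choroid plexus in hippocampus without replicate 1 at 18 months (adjusted p = 2.09e-06; unadjusted 4.58e-07, up to 0.809 without other libraries) and for synapse in hippocampus without replicate 2 at 2 months (adjusted p = 0.00176; unadjusted 0.00044, up to 0.716).

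Over all alternatives, 2169 values of 185 named results gave 1921 the same, 208 weaker, 40 stronger and 0 reversed, and 1003 values of 92 list results gave 901, 63, 34 and 5. Leaving out libraries, 1658 values of named results gave 1271 the same, 381 weaker, 6 stronger and 0 reversed, and 828 of lists 759, 16, 51 and 2. Of 29 named genes called in cortex 9 stayed called under every alternative and 27 after removal of GC and length trends, of 12 in hippocampus 2 and 6, and of 37 in kidney 21 and 26, with C1qa in kidney among those lost after that removal.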

Other observations

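The look at pituitary, hypothalamic and choroid plexus transcripts of single libraries was chosen only after the values were seen.

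Replicate numbers pair across tissues in most comparisons, but not across ages. At one age the libraries of 2 tissues with the same number had the highest correlation of their deviations in 21 of 27 cases (median 0.118, from -0.425 to 0.333), against 6 of 27 for the same number at 2 ages in one tissue (median -0.0348). Only 15 of the 27 pairs across tissues exceeded 0.1, and for kidney with cortex at 18 months the correlation was -0.425 for replicate 1 (best other number 0.477) and -0.165 for replicate 3 (0.372). Where numbers pair, the tissues of an animal share part of their variation, and overlaps between tissues are not independent evidence.

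Pituitary and hypothalamic transcripts varied between brain libraries of 2 months, with Gh at 520.3 FPKM in hippocampus replicate 3 against 11.81 and 10.75 FPKM in replicates 1 and 2, and at 199.88 FPKM in cortex replicate 3 of the same animal. Ttr was 7970.64 FPKM in replicate 1 of hippocampus at 18 months and 63.26 and 146.85 FPKM in replicates 2 and 3. Thalamus and striatum markers lay below 0 in all 10 genes in hippocampus, and striatum markers above 0 in all 10 genes in cortex. How tissue was dissected was not analysed here.

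Reads shared by near-identical copies add uncertainty to C4a and C4b, Rpl37rt, Rpl genes, Srp9, Serpina1a, Bcl2a1b and Selenbp2. Mitochondrially encoded and sex-chromosome genes were not analysed here, nor were sequence variants or reads. Sex of the animals and strand setting are not given in the sources used here.

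At 18 against 2 months the named genes called under every alternative in which they were tested and whichever library was left out were Capn11, Mb, Myl2 and Tdg in cortex, Tdg in hippocampus, and C1qb, C4b, Camk1g, Capn11, Ccl8, Igfbp2, Kcnh6, Laptm5, Mcm6, Pld4, Rbm3, Selenbp2, Serpina1a and Tdg in kidney. Of these, C4b, Camk1g, Ccl8, Igfbp2, Mcm6 and Tdg were not tested at a mean of at least 5 FPKM. The fall of Tdg is matched by the rise of a model without a symbol (0.0467 to 9.80 FPKM in cortex), so it is not settled as a change of the gene. The rise of Kcnh6 went with the fall of another such model and is not settled either. Measuring Tdg and Rpl29 apart from the models that mirror them, in more animals per age, would help to tell whether these changes are of the genes themselves. A test of C4 protein would show whether it follows C4b.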
